A study of Mus musculus with 12 samples.

How the data were processed

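RNA was measured in 12 tumors grown from the mouse sarcoma line BVMA01R, which carries a Myf5-Cre driver and lacks Trp53 and Ass1, in female C57BL/6J mice. The labels give 4 groups of 3 libraries: no treatment, chloroquine, ADI-PEG20, and ADI-PEG20 plus chloroquine. Per the labels, total RNA was extracted from frozen tumors and ribosomal RNA was depleted before library preparation. The submitters' processing notes name the mouse build mm10, bcl2fastq, STAR 2.5.1a, Subread featureCounts 1.4.6-p5, Salmon 0.8.2, edgeR and limma, without giving the role or order of each.

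The authors deposited a merged table of 16386 lines covering 16335 distinct genes, with 51 repeats of an identifier already listed, of which the earliest line was kept. Its deposited values per library are log2 CPM, computed as log2 of the reads plus 0.5, scaled by an effective library size. The worth of 1 read was recovered from each column, and 100% of the values under 2000 reads then came to within 0.02 of a whole number of reads. The deposited mean expression is the plain mean of the 12 columns, on the log2 scale. Per the file headers, the same table holds log2 fold changes with 95% limits, a signed linear fold change (a score), and a p-value with its adjusted p-value for each comparison. The authors' fold changes are not plain differences of group means. A voom fit with library quality weights on the recovered reads gave fold changes close to those the authors deposited, with r from 0.9975 to 0.9996 across genes over the comparisons.

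The authors also deposited results for 246 KEGG gene sets in each of 3 comparisons with no treatment. The deposited column headed as a mean log2 fold change holds a test statistic (a score) instead: its median ratio to the mean log2 fold change of the listed genes was 8.382 to 11.71. The deposited p-value of each set is one-sided, its adjusted p-value is taken over 246 sets for each direction, and the tool behind it is not named in the processing notes. The set size in these tables counts genes.

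The recovered reads came to 15501998 to 28410940 per library, and the effective library size ran from 12590137 (ADI-PEG20 1) to 31280299 (ADI-PEG20 2), so that 1 read was worth 0.0320 to 0.0794 CPM. The lowest total of any gene over the 12 libraries was 85 reads, so the table had already lost its low genes and no further filter was applied. At these depths counting error was small beside the spread between tumors for genes with many reads. Among genes with more than 20 reads in a pair of replicates, the chi-square per degree of freedom was 24.75 to 279.3, where counting error alone gives about 1. Genes with many reads weigh most in this value, so it does not cover scarce genes. Standard errors (SE) come from the spread between libraries, except where an SE is said to be over the genes of a list.

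Each comparison was fitted with limma 3.58.1 in R 4.3.3 on the deposited log2 CPM, with all 12 libraries in 1 fit, no covariate, and moderated statistics with a trend in expression. The 6 contrasts were ADI-PEG20, chloroquine and the combination against no treatment, the combination against each single drug, and the interaction, which is the effect of ADI-PEG20 with chloroquine minus its effect without. All tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over 16335 genes with a threshold of 0.05. The replicate numbers 1 to 3 were not used as pairs: the design fixed in advance had no replicate block. The labels do not say that libraries sharing a number belong together. Within each group the replicate numbers follow the order of the sample description numbers, so libraries that share one tend to lie near each other in that order. The labels do not say that each library is a separate animal, so every p-value measures the spread between these samples alone.

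Before the data were examined, the tests, 38 gene lists and the rule for naming genes were fixed. The lists cover 21 programs, 16 cell types and 1 set of RNA quality and mitochondrial transcripts, with 622 of their 688 genes in the table. None was chosen on these samples. The programs were arginine and urea cycle enzymes, amino acid transporters, integrated stress response targets, endoplasmic reticulum chaperones, polyamine metabolism, pyrimidine and purine synthesis, autophagy, lysosome, macropinocytosis, cholesterol synthesis, glycolysis, hypoxia response, oxidative phosphorylation, G1 to S, G2 and mitosis, type I interferon response, interferon gamma response, inflammatory cytokines, extracellular matrix, phospholipase A2 and angiogenesis. Lists were tested with limma's camera at a preset correlation of 0.01, which compares the genes of a list with all other genes, and adjusted over the 38 lists within a comparison. Camera with an estimated correlation and fry were run as alternatives. Lists share few genes: amino acid transporters and stress response targets share 2, and glycolysis and hypoxia response share 1.

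The rule for named genes took genes past the threshold. Where fewer than 5 passed in a direction, it took the 6 with the smallest p in that direction, leaving out predicted genes, pseudogenes, small RNAs and antigen receptor segments. It added up to 4 members of each list described, those with the smallest p, and Ass1 and Trp53. Positions came from GENCODE M21 on GRCm38, which holds 16330 of the 16335 genes. Figures were drawn with matplotlib 3.10.9.

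The gene test was tried on simulated data in which genes vary independently of each other, unlike in tumors: it recovered 36% of 100 genes changed 2-fold and 73% of 100 genes changed 4-fold, with 4 unchanged genes called. A list shifted by 0.5 on the log2 scale was recovered with an adjusted p of 5.85e-16, and 0 other lists were called. Alternatives covered library weights, a replicate block, only the compared groups in the fit, a stricter filter of 5 CPM in 3 libraries, another scaling, an added 2-fold threshold, the authors' adjusted p-values, and leaving out each library. Fits with voom weights, fits without ADI-PEG20 1 and untreated 2, and the other scaling for gene lists were added after the values were seen. No library was left out of the tests described first.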

Results

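The tumors were examined for what arginine depletion by ADI-PEG20, lysosomal inhibition by chloroquine, and both together change in a sarcoma that lacks argininosuccinate synthase. Ass1, the enzyme that lets cells rebuild arginine from citrulline (ENSMUSG00000076441, chromosome 2, 31470207 to 31520672, GRCm38), gave reads in all 12 libraries, 153 to 397 reads or 6.85 to 18.9 CPM. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) gave 326 to 756 reads, or 13.1 to 26.8 CPM. Reads counted per gene do not show which part of a gene was deleted, and host cells in a tumor carry intact copies. Ass1 differed from untreated tumors by 0.50 with ADI-PEG20 (SE 0.30, adjusted p = 0.65), 0.63 with chloroquine (adjusted p = 1) and 0.51 with both (adjusted p = 0.65) on the log2 scale. The same differences for Trp53 were 0.44, 0.16 and 0.25, and none passed.

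With ADI-PEG20, the pegylated arginine deiminase that breaks down arginine outside cells, amino acid transporters and targets of the integrated stress response rose as groups relative to untreated tumors. The transporters went from a mean of 5.10 (SD 0.15, n = 3) to 5.55 log2 CPM (SD 0.05, n = 3), a difference of 0.45 with 14 of 16 genes higher (camera adjusted p = 0.000032, or adjusted p = 0.33 with an estimated correlation). Slc7a3, a transporter of arginine and lysine (ENSMUSG00000031297, chromosome X, 101079210 to 101086020), averaged 5.94 CPM in untreated and 32.5 CPM in ADI-PEG20 tumors, a log2 difference of 2.44 (SE 0.47, adjusted p = 0.48), with no overlap between the 3 and 3 libraries. The stress response targets, which the transcription factor ATF4 drives when amino acids run short, rose by a mean of 0.36 with 20 of 28 higher (camera adjusted p = 0.00014, or adjusted p = 0.43 with an estimated correlation). Among them Cth, which makes cysteine from cystathionine, differed by 1.98 (SE 0.52), Trib3 by 1.64 (SE 0.49), Aldh1l2 by 0.99 (SE 0.30) and Sesn2 by 0.77 (SE 0.22). Adjusted over the list alone, 3 transporters and 5 stress response targets passed, and 0 over all genes. Without untreated 1 the mean of the stress response list was 0.18 (camera adjusted p = 0.017).

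Several immune lists were higher in the ADI-PEG20 tumors, while neutrophil markers (-0.14, camera adjusted p = 0.99), natural killer cell markers (0.51, 0.25) and inflammatory cytokines (0.25, 0.068) did not pass. The interferon gamma and antigen presentation list rose by a mean of 1.04, with 21 of 22 genes higher and 10 passing adjusted over the list alone (0 over all genes). Its examples were the class II regulator Ciita (1.63, SE 0.46) and the class II genes H2-Eb1 (2.08, SE 0.60), H2-Aa (1.97, SE 0.58) and Cd74 (1.87, SE 0.56). Markers of T cells rose by a mean of 1.13 with 18 of 18 higher, those of dendritic cells by 0.83 with 10 of 11 higher, and those of macrophages and monocytes by 0.50 with 16 of 19 higher and 6 passing adjusted over the list alone. Macrophage examples were the Fc receptor Fcgr1 (1.19, SE 0.26), the complement genes C1qc (0.65, SE 0.18) and C1qb (0.71, SE 0.20), and Ccr2 (1.19, SE 0.36). The T cell transcripts were scarce, at a list mean of 0.07 log2 CPM in untreated tumors (SD 0.43, n = 3) and 1.19 with ADI-PEG20 (SD 0.14, n = 3). Csf1, the growth factor of macrophages (chromosome 3, 107741048 to 107760469), differed by 0.76 (SE 0.16, adjusted p = 0.48). The camera adjusted p was 1.5e-12 for the interferon gamma list, 0.0000014 for T cells, 0.0014 for dendritic cells and 3.9e-08 for macrophages, and each list had an adjusted p = 0.33 with an estimated correlation.

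2 further immune lists passed with ADI-PEG20 but rested on single libraries. All 26 genes of the type I interferon list were higher, by a mean of 0.50 (camera adjusted p = 0.0000017, or adjusted p = 0.57 with an estimated correlation), led by the antiviral enzymes Oas2 (1.25, SE 0.45) and Oas3 (1.20, SE 0.44). Without untreated 2 this mean was 0.24 (adjusted p = 0.054), and without untreated 3 it was 0.84. Markers of B and plasma cells rose by 1.05, with Igkc at 2.87 (SE 0.83) and Ighm at 2.03 (SE 0.62), and 3 of 7 genes passed adjusted over the list alone (camera adjusted p = 0.01, or adjusted p = 0.33 with an estimated correlation). Their call ended without untreated 2 (0.78, adjusted p = 0.054), ADI-PEG20 2 (0.75, adjusted p = 0.058) or ADI-PEG20 3 (0.81, adjusted p = 0.12), and the mean was 1.59 without ADI-PEG20 1.

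Genes of glucose metabolism and low oxygen were lower with ADI-PEG20. Glycolysis fell by a mean of 0.53 with 17 of 17 genes lower, from 7.92 (SD 0.39, n = 3) to 7.39 log2 CPM (SD 0.10, n = 3), and the hypoxia response fell by 0.59 with 14 of 15 lower. Examples were lactate dehydrogenase Ldha (-0.70, SE 0.21), the glucose transporter Slc2a1 (-1.01, SE 0.37), Ndrg1 (-0.92, SE 0.23) and the collagen hydroxylases P4ha1 (-0.71, SE 0.19) and P4ha2 (-0.71, SE 0.18). On the glycolysis list the libraries overlapped, with untreated 3 at 7.478 and ADI-PEG20 3 at 7.504 log2 CPM. By camera, the adjusted p was 6.2e-09 for glycolysis and 0.0000017 for hypoxia response, and both had an adjusted p = 0.33 with an estimated correlation. Of the hypoxia genes 6 passed adjusted over the list alone, of the glycolysis genes 0, and 0 of either over all genes. Tnc, an extracellular matrix glycoprotein, was lower by 0.95 (SE 0.21), the fatty acid carrier Fabp5 by 1.09 (SE 0.25) and the phosphatidate phosphatase Lpin3 by 0.87 (SE 0.20), each with an adjusted p of 0.48.

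Growth and mitochondrial lists also fell with ADI-PEG20, by less. All 22 genes of G2 and mitosis were lower, by a mean of -0.30, with the kinases Aurka at -0.51 (SE 0.17) and Plk1 at -0.49 (SE 0.19). The G1 to S list fell by 0.23 with 17 of 20 lower, oxidative phosphorylation by 0.20 with 23 of 27 lower, and cholesterol synthesis by 0.30 with 20 of 24 lower. In camera's test the adjusted p was 0.0000074, 0.00077, 0.0001 and 0.00028 in that order. With an estimated correlation the adjusted p = 0.53 for G2 and mitosis and for oxidative phosphorylation, and the adjusted p = 0.55 for G1 to S and for cholesterol synthesis. ADI-PEG20 1 and untreated 1 carried part of this: without ADI-PEG20 1 the means were -0.19, -0.15, -0.11 and -0.04, the last no longer called (adjusted p = 0.3), and without untreated 1 those of G2 and mitosis and of oxidative phosphorylation were -0.16 and -0.09. Cholesterol synthesis was at -0.47 without ADI-PEG20 2.

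ADI-PEG20 1 stood apart from the other libraries: it held the most transcripts of muscle and fat, the most genes at 0 reads (120, against 7 to 43 elsewhere) and the lowest median correlation with the rest (0.920). Its skeletal muscle list averaged 7.16 log2 CPM, against 2.98 and 2.08 in the other ADI-PEG20 tumors. Gm26917, an abundant noncoding RNA, took 22.8% of its reads, against 16.4% in untreated 2 and 5.09% to 9.86% in the remaining libraries. The adipocyte list was called higher with ADI-PEG20 (mean 1.35, camera adjusted p = 0.00077, or adjusted p = 0.5 with an estimated correlation), with Lpl at 1.39 (SE 0.33) and Pparg at 1.20 (SE 0.33), the 2 that passed adjusted over the list alone. Without ADI-PEG20 1 its mean was 0.32 (adjusted p = 0.19), without untreated 2 it was 0.86, without both of these it was -0.17 (adjusted p = 0.63), and without ADI-PEG20 2 it was 2.15. Erythroid genes were called lower (-1.44, camera adjusted p = 0.0059, or adjusted p = 0.53 with an estimated correlation). That call ended without untreated 2 (-0.88, adjusted p = 0.096), ADI-PEG20 2 (-1.29, adjusted p = 0.058) or ADI-PEG20 3 (-1.12, adjusted p = 0.065).

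No single gene passed limma's test for ADI-PEG20 against no treatment over 16335 genes: 1357 genes had an unadjusted p under 0.05, 845 higher and 512 lower, where chance gives 817. The same 6 libraries split otherwise gave up to 2090, and 6 of the 10 splits, the real one included, gave at least 1357. The smallest adjusted p was 0.48, and 0 genes passed with voom weights, with library weights, or in the authors' table. The genes with the smallest p among those higher were Slc7a3, the actin-binding protein Avil (2.38, SE 0.46), Fam129a (1.23, SE 0.24), the membrane scaffold Ank2 (0.66, SE 0.14), Csf1 and the lectin receptor Clec4a1 (1.90, SE 0.41). Among those lower they were Apob (-2.56, SE 0.51), Depdc1b (-1.50, SE 0.30), Tnc, Lpin3, Fabp5 and Pcolce2 (-1.20, SE 0.28). The 3 and 3 libraries did not overlap for 10.1% of genes, where chance gives 10%. Leaving out untreated 3 let 1 gene pass, the apelin receptor Aplnr (1.62, adjusted p = 0.039), a gene outside the naming rule and named after its values were seen.

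**Figure D1:**
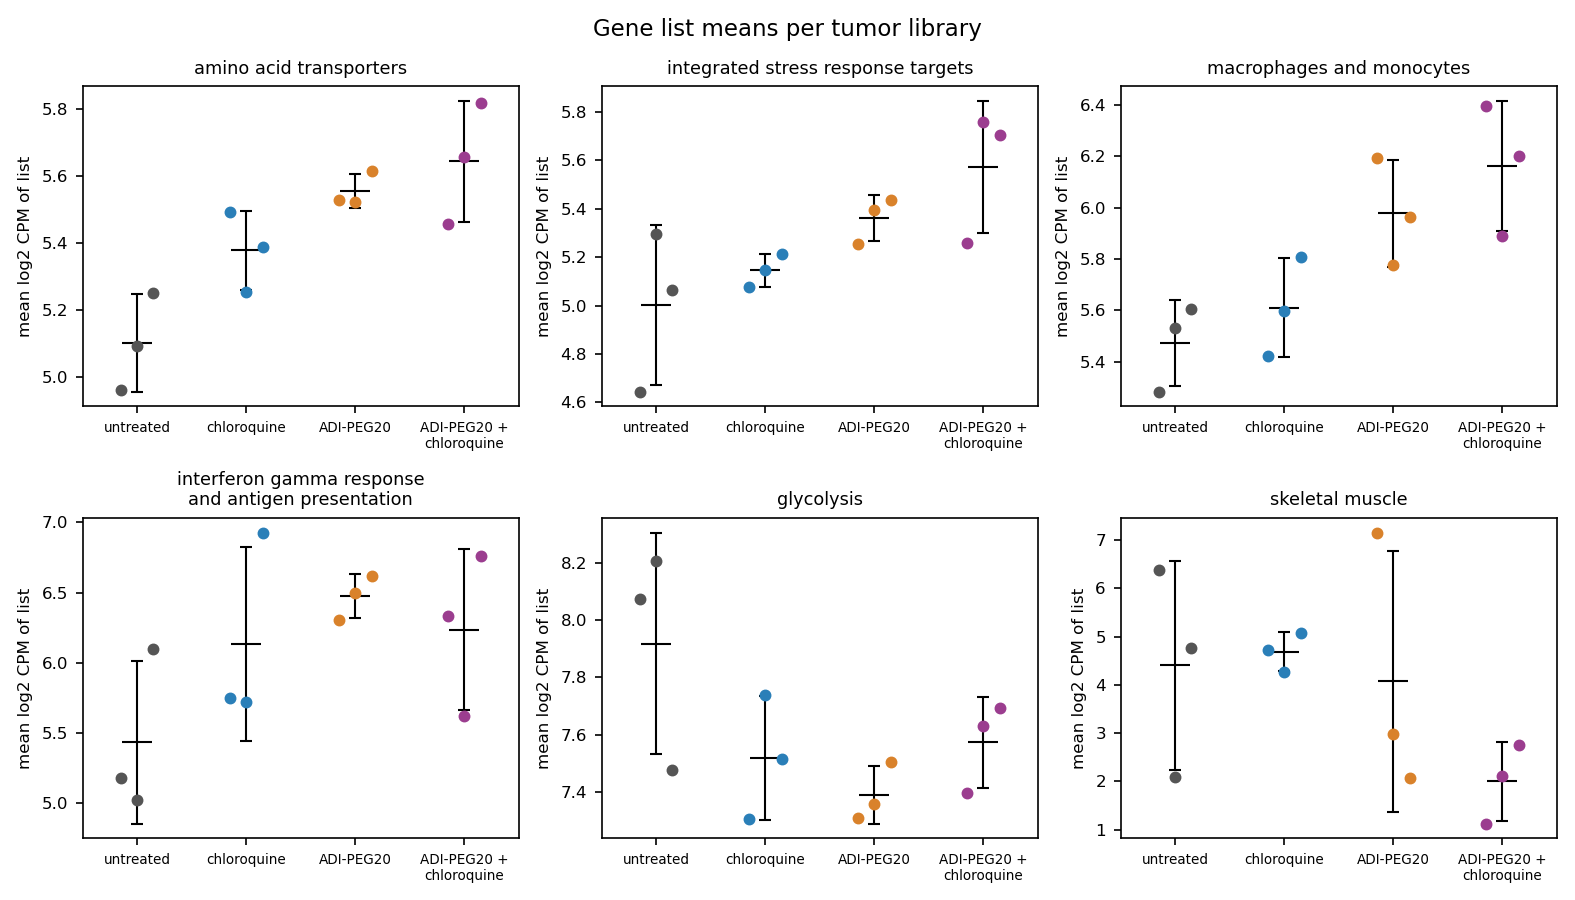
Mean log2 CPM of 6 gene lists (y axis) in the 4 treatment groups (x axis), with 1 point per tumor library and a bar at the mean with the SD (n = 3). Amino acid transporters averaged 5.10 in untreated and 5.64 in doubly treated tumors and macrophage markers 5.47 and 6.16, while skeletal muscle genes spread from 1.12 to 7.16 between libraries.

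With chloroquine, an inhibitor of lysosomal acidification, interferon genes rose as groups relative to untreated tumors. All 26 type I interferon genes were higher, by a mean of 0.67, and all 22 genes of the interferon gamma list, by 0.70. The libraries overlapped on both lists. Untreated 3 was at 5.77 and 6.10 log2 CPM, above chloroquine 1 at 5.59 and 5.75 and chloroquine 2 at 5.51 and 5.72. Oas2 differed by 1.4 (SE 0.45), the T cell attractant Cxcl9 by 1.73 (SE 0.45) and the peptide transporter Tap1 by 0.94 (SE 0.39), and 1 interferon gamma gene, Cxcl9, passed adjusted over the list alone. Glycolysis fell by 0.40 with 17 of 17 lower and the hypoxia response by 0.48 with 13 of 15 lower, with Slc2a1 at -0.81 (SE 0.37) and P4ha1 at -0.56 (SE 0.19). For glycolysis untreated 3 was at 7.478 log2 CPM, below chloroquine 2 at 7.739 and chloroquine 3 at 7.515. Amino acid transporters rose by 0.28 with 14 of 16 higher, Slc7a5 among them (0.60, SE 0.23). Camera gave an adjusted p of 9.4e-16, 1.9e-10, 7.8e-09, 0.000022 and 0.00058 in that order, and each had an adjusted p = 0.44 with an estimated correlation. Single libraries moved these means: without untreated 2 the type I interferon mean was 0.41, glycolysis -0.26 and hypoxia -0.31, without untreated 3 glycolysis was -0.62, without chloroquine 1 hypoxia was -0.25, and without chloroquine 3 the interferon gamma mean was 0.30 (adjusted p = 0.0079).

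Markers of natural killer, T and dendritic cells were also higher with chloroquine. Natural killer cell markers rose by a mean of 1.07 with 7 of 8 higher, Eomes at 1.98 (SE 0.67) and Klrk1 at 1.57 (SE 0.65) among them, T cell markers by 0.73 with 17 of 18 higher, and dendritic cell markers by 0.50 with 10 of 11 higher. Keratinocyte genes fell by 0.86 with 10 of 12 lower. The camera adjusted p was 0.0047, 0.000063, 0.019 and 0.03, with an adjusted p = 0.44 for the first 3 lists and an adjusted p = 0.71 for keratinocytes with an estimated correlation. The T cell call ended without chloroquine 3 (0.30, adjusted p = 0.11), and the dendritic cell call without chloroquine 3 (0.17, adjusted p = 0.45) or untreated 2 (0.43, adjusted p = 0.059). The keratinocyte mean was -1.84 without untreated 1 and -1.34 without chloroquine 3, and its call ended without untreated 2 (-0.63, adjusted p = 0.11), untreated 3 (-0.12, adjusted p = 0.56) or chloroquine 2 (-0.52, adjusted p = 0.31).

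The lists closest to the known action of chloroquine did not pass: autophagy genes differed by a mean of -0.03 (camera adjusted p = 0.36) and lysosome genes by -0.05 (0.72). The genes with the smallest p among those higher were the imprinted gene Mest (1.10, SE 0.26), Cxcl9, the nucleoside transporter Slc28a2 (1.61, SE 0.42), N-cadherin Cdh2 (0.73, SE 0.21), Spock2 (1.61, SE 0.47) and the alanine transaminase Gpt2 (0.76, SE 0.22). Those lower were the stromelysin Mmp10 (-2.87, SE 0.64), the AMP deaminase Ampd3 (-0.81, SE 0.19), Tspyl5 (-0.90, SE 0.23), Id2 (-0.85, SE 0.24), Cacng4 (-1.54, SE 0.44) and the potassium channel Kcnk2 (-0.95, SE 0.27). Each had an adjusted p of 1 in limma's test. 0 genes passed, 555 had an unadjusted p under 0.05 where chance gives 817, and 0 passed with voom weights, with library weights or in the authors' table. The libraries did not overlap for 7.41% of genes, where chance gives 10%. Camera called 9 lists for chloroquine against no treatment. The same 6 libraries split otherwise called up to 18, and 9 of the 10 splits, the real one included, called at least 9.

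Tumors given both drugs differed from untreated tumors in the same lists of amino acid supply and stress, with larger means than those of either drug alone. Amino acid transporters rose by 0.54 with 14 of 16 higher, and stress response targets by 0.57 with 23 of 28 higher. Macrophage markers rose by 0.69 with 18 of 19 higher, from 5.47 (SD 0.17, n = 3) to 6.16 log2 CPM (SD 0.25, n = 3). Slc7a3 averaged 38.7 CPM, 2.64 above untreated tumors on the log2 scale (SE 0.47, adjusted p = 0.19), Cth was higher by 2.73 (SE 0.52, adjusted p = 0.2), the cystine transporter Slc7a11 by 1.55 (SE 0.42), the glycine transporter Slc6a9 by 1.13 (SE 0.23), and the serine and one-carbon enzymes Psat1 by 0.80 (SE 0.19) and Mthfd2 by 0.89 (SE 0.21). The mannose receptor Mrc1 was higher by 1.19 (SE 0.26), Fcgr1 by 1.20 (SE 0.26), Csf1r by 0.75 (SE 0.19), and the ligand Csf1 by 0.80 (SE 0.16). By camera, the adjusted p was 7.9e-07, 1.5e-09 and 1.1e-12, with an adjusted p = 0.17 for transporters and macrophages and an adjusted p = 0.25 for stress response targets with an estimated correlation. Adjusted over the list alone 4, 11 and 10 members passed, and 0 over all genes. By fry the transporters and the macrophages passed, each with an adjusted p of 0.045. Whether the means with both drugs differ from those with ADI-PEG20 alone is tested by the contrast of those groups, where transporters differed by 0.09 (adjusted p = 0.27), stress response targets by 0.21 (adjusted p = 0.0036, or adjusted p = 0.68 with an estimated correlation, a call that ended without doubly treated 2 at 0.12, adjusted p = 0.14, and a mean of 0.37 without doubly treated 1) and macrophages by 0.18 (adjusted p = 0.054).

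Interferon, lysosome and cytokine lists rose with both drugs relative to no treatment. The interferon gamma list rose by 0.80 with 22 of 22 higher, B2m at 0.98 (SE 0.35) and H2-Aa at 1.58 (SE 0.58), and the lysosome list by 0.16 with 30 of 36 higher, the peptidase Tpp1 at 0.53 (SE 0.15) and the transcription factor Mitf at 0.73 (SE 0.22). The type I interferon list rose by 0.48 with 25 of 26 higher, and inflammatory cytokines by 0.40 with 12 of 18 higher, the monocyte attractants Ccl2 (0.88, SE 0.29), Ccl7 (0.80, SE 0.23) and Ccl8 (1.89, SE 0.64) among them. In camera's test the adjusted p was 1.2e-08, 0.000093, 0.0000035 and 0.0041 in that order. With an estimated correlation the adjusted p = 0.46 for all but the type I interferon list, whose adjusted p = 0.62. Adjusted over the list alone, 4 cytokine genes passed, and 0 over all genes. The cytokine call ended without untreated 1 (0.18, adjusted p = 0.14) or doubly treated 3 (0.21, adjusted p = 0.094), and the type I interferon call ended without untreated 2 (0.21, adjusted p = 0.071). The type I mean was 0.81 without untreated 3, 0.30 without doubly treated 1 and 0.80 without doubly treated 2.

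Muscle transcripts were lower in the doubly treated tumors. The 17 skeletal muscle genes were all lower than in untreated tumors, by a mean of -2.41, and the 10 genes of myogenic progenitors, also all lower, by -0.86. Examples were the calcium pump Atp2a1 (-3.98, SE 1.62), the slow myosin Myh7 (-2.88, SE 1.14), Des (-1.34, SE 0.49) and the transcription factor Msc (-1.81, SE 0.59). Untreated tumors differed widely among themselves, with skeletal muscle lists at 6.37, 2.08 and 4.77 log2 CPM, against 1.12, 2.12 and 2.76 in the doubly treated tumors. Camera gave an adjusted p of 5.2e-08 for muscle and 0.00056 for progenitors, both with an adjusted p = 0.46 with an estimated correlation. Without untreated 1 the means were -1.43 and -1.35, and without untreated 3 the progenitor mean was -0.37 and no longer called (adjusted p = 0.06).

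Glycolysis fell by 0.35 in the doubly treated tumors with 17 of 17 lower, Aldoa at -0.56 (SE 0.23) and Ldha at -0.50 (SE 0.21) among them (camera adjusted p = 0.000072, or adjusted p = 0.46 with an estimated correlation). Its mean was -0.20 without untreated 2 and -0.57 without untreated 3. The libraries overlapped: untreated 3 was at 7.478 log2 CPM, below doubly treated 2 at 7.63 and doubly treated 3 at 7.694. Another 8 lists passed against no treatment with calls that rested on single libraries: adipocytes (0.81, camera adjusted p = 0.033), B cells (0.99, 0.045), dendritic cells (0.67, 0.041), T cells (0.61, 0.03), endoplasmic reticulum chaperones (0.14, 0.045), cholesterol synthesis (-0.17, 0.03), hypoxia response (-0.22, 0.041) and oxidative phosphorylation (-0.09, 0.048). With an estimated correlation the adjusted p = 0.46 for B and dendritic cells, the adjusted p = 0.62 for adipocytes, T cells and hypoxia, the adjusted p = 0.66 for chaperones, and the adjusted p = 0.7 for cholesterol synthesis and oxidative phosphorylation. Without untreated 1 no longer called were adipocytes (0.86, adjusted p = 0.056), B cells (0.93, 0.13), dendritic cells (0.58, 0.092), T cells (0.42, 0.26), cholesterol synthesis (-0.08, 0.37), hypoxia (-0.21, 0.14) and oxidative phosphorylation (0.02, 0.92), and the chaperone mean was 0.24. Without untreated 2 no longer called were adipocytes (0.32, adjusted p = 0.13), B cells (0.72, 0.12), dendritic cells (0.60, 0.12), chaperones (0.00, 0.89) and hypoxia (-0.04, 0.3). Without untreated 3 the means of adipocytes, hypoxia and oxidative phosphorylation were 1.25, -0.39 and -0.14. Without doubly treated 1 no longer called were adipocytes (0.11, adjusted p = 0.37), B cells (0.83, 0.14), dendritic cells (0.62, 0.064), T cells (0.50, 0.11), chaperones (0.13, 0.11), hypoxia (-0.06, 0.4) and oxidative phosphorylation (-0.09, 0.056). Without doubly treated 2 the chaperone call ended (0.13, adjusted p = 0.11), and without doubly treated 3 no longer called were B cells (0.83, adjusted p = 0.095), dendritic cells (0.54, 0.14), T cells (0.43, 0.14), cholesterol synthesis (-0.14, 0.094) and oxidative phosphorylation (-0.06, 0.2), while hypoxia was at -0.38. Leaving out libraries of the other groups also ended calls at unchanged means: oxidative phosphorylation without chloroquine 1 (adjusted p = 0.052), chloroquine 3 (0.051), ADI-PEG20 1 (0.067), ADI-PEG20 2 (0.051) or ADI-PEG20 3 (0.057), chaperones without chloroquine 3 (0.051), hypoxia without ADI-PEG20 1 (0.054) and B cells without ADI-PEG20 3 (0.063).

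No gene passed limma's test for both drugs against no treatment, with 1413 genes at an unadjusted p under 0.05 (767 higher, 646 lower) where chance gives 817, and a smallest adjusted p of 0.19. The lowest p belonged to Gnao1, a G protein alpha subunit (ENSMUSG00000031748, chromosome 8, 93809966 to 93969388), lower by 1.12 (SE 0.17), the membrane metalloprotease Mmp15 (ENSMUSG00000031790, chromosome 8, 95352268 to 95375080), lower by 1.41 (SE 0.23), and the guidance cue netrin 1, Ntn1, lower by 1.34 (SE 0.23). Itgb2l (-1.84, SE 0.34), Igsf5 (-1.79, SE 0.34) and Tnc (-1.12, SE 0.21) followed among those lower, and Ank2 (0.79, SE 0.14), Lst1 (1.88, SE 0.33), Gpt2 (1.24, SE 0.22) and Fam129a (1.25, SE 0.24) among those higher besides Slc7a3 and Cth. Their adjusted p was 0.19 or 0.2. The libraries did not overlap for 15.4% of genes, where chance gives 10%. Counts of passing genes were 0 with voom weights, with library weights and in the authors' table. They were 8 with the replicate number as a block and 17 without ADI-PEG20 1 and untreated 2.

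**Figure D2:**
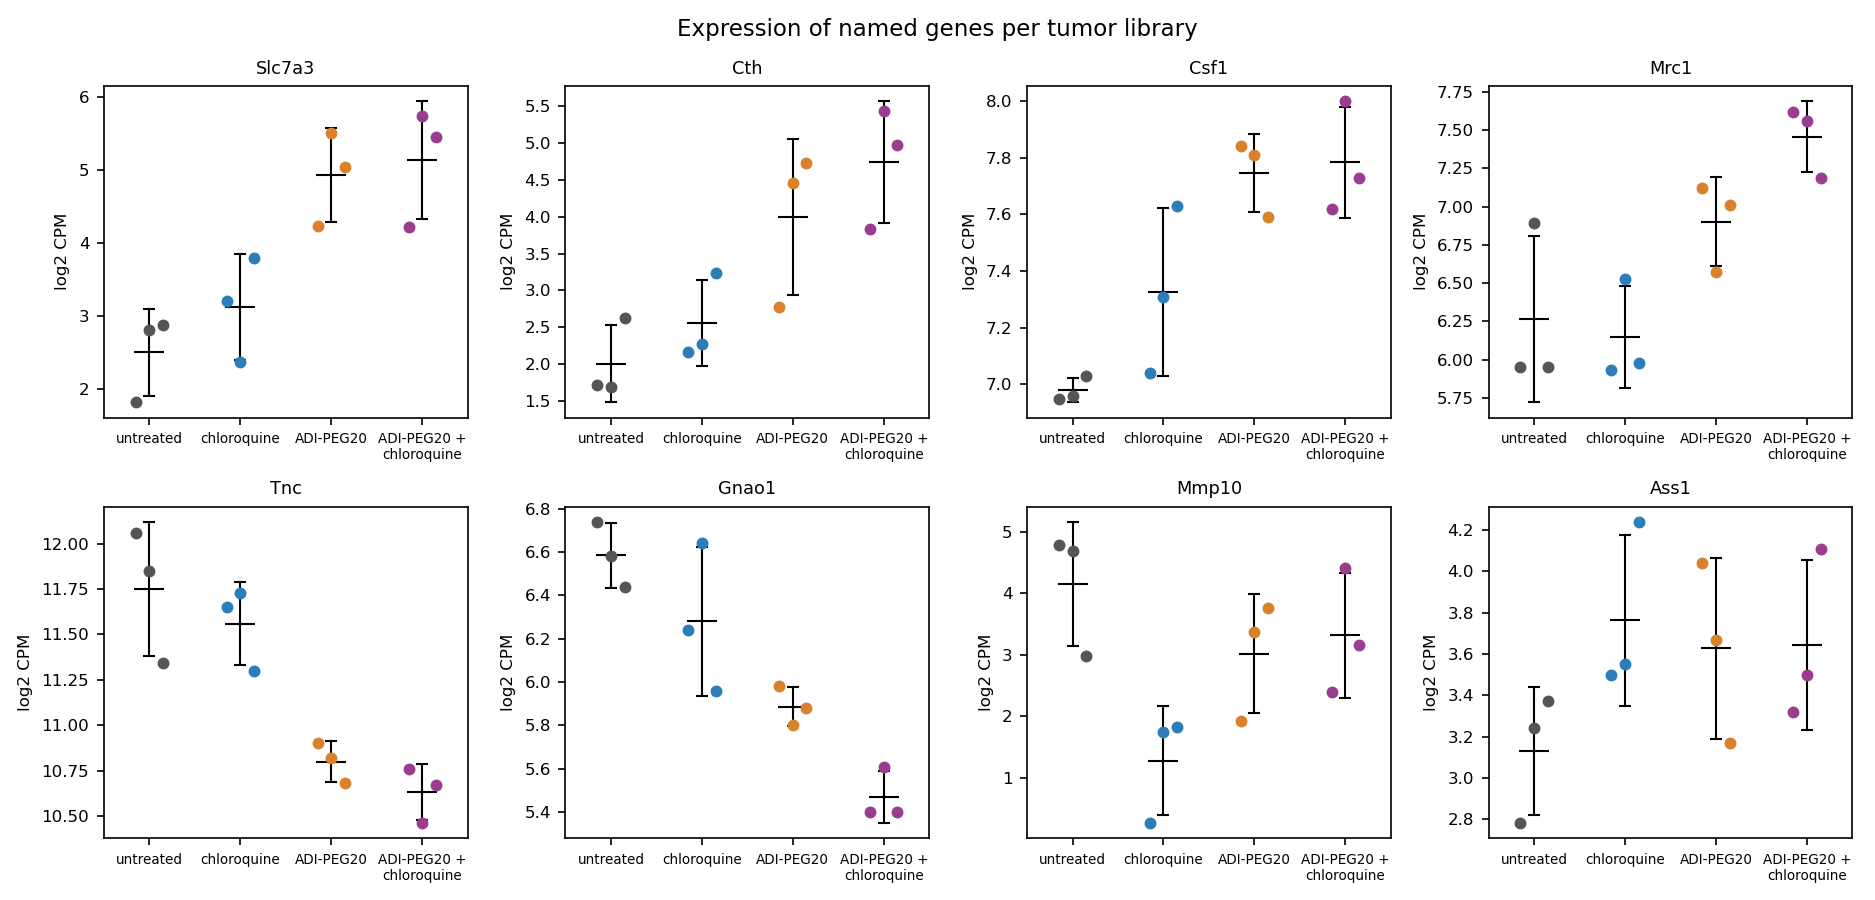
Log2 CPM (y axis) of Slc7a3, Cth, Csf1, Mrc1, Tnc, Gnao1, Mmp10 and Ass1 in the 4 treatment groups (x axis), with 1 point per tumor library and a bar at the mean with the SD (n = 3). Slc7a3 averaged 2.5 in untreated, 3.13 in chloroquine, 4.93 in ADI-PEG20 and 5.14 in doubly treated tumors, and Tnc 11.75, 11.56, 10.80 and 10.63.

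Adding chloroquine to ADI-PEG20 went with higher cell cycle and erythroid transcripts and lower muscle transcripts. The G1 to S list rose by 0.22 with 17 of 20 higher and the erythroid list by 1.58 with 6 of 6 higher, Hbb-bt at 2.03 (SE 0.84). G2 and mitosis rose by 0.19, Aurka at 0.39 (SE 0.17), and the hypoxia response by 0.38, Kdm3a at 0.62 (SE 0.22). Skeletal muscle genes were lower by a mean of -2.07 with 17 of 17 lower, Myh7 at -2.77 (SE 1.14), and T cell markers by -0.52 with 18 of 18 lower, Pdcd1 at -1.78 (SE 0.80). The camera adjusted p was 0.00046, 0.00042, 0.0036, 0.0031, 1.7e-07 and 0.0066 in that order, and each had an adjusted p = 0.68 with an estimated correlation. Without ADI-PEG20 1 the skeletal muscle mean was -0.53 (adjusted p = 0.061), G2 and mitosis 0.08 (adjusted p = 0.061) and G1 to S 0.14 (adjusted p = 0.0017). Without doubly treated 1 G2 and mitosis was at 0.08 (adjusted p = 0.3) and the erythroid list at 0.89 (adjusted p = 0.032), without doubly treated 2 the T cell mean was -0.22 (adjusted p = 0.23), and without doubly treated 3 hypoxia was at 0.22 (adjusted p = 0.11).

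The other lists called between the doubly treated and the ADI-PEG20 tumors rested on single libraries. They were pyrimidine and purine (nucleotide) synthesis (0.14, camera adjusted p = 0.044), lysosome (0.10, 0.03), glycolysis (0.18, 0.037), RNA quality and mitochondrial transcripts (0.24, 0.022) and myogenic progenitors (-0.84, 0.03), each with an adjusted p = 0.68 with an estimated correlation. Msc was at -1.49 (SE 0.59), Mitf at 0.54 (SE 0.22), the acid ceramidase Asah1 at 0.44 (SE 0.20) and mt-Co3 at 0.46 (SE 0.23). Without ADI-PEG20 1 no longer called were nucleotide synthesis (0.02, adjusted p = 0.61), glycolysis (0.14, 0.061), RNA quality (-0.01, 0.73) and myogenic progenitors (-0.45, 0.2). Without ADI-PEG20 2 no longer called were lysosome (0.04, adjusted p = 0.6), glycolysis (0.17, 0.17) and myogenic progenitors (-0.65, 0.47), while nucleotide synthesis was at 0.26. Without ADI-PEG20 3 the nucleotide synthesis call ended (0.14, adjusted p = 0.23), with lysosome at 0.19 and myogenic progenitors at -1.41. Without doubly treated 1 nucleotide synthesis was at 0.11 (adjusted p = 0.15) and glycolysis at 0.27. Without doubly treated 2 no longer called were nucleotide synthesis (0.13, adjusted p = 0.13), glycolysis (0.15, 0.16) and RNA quality (0.13, 0.24), and without doubly treated 3 lysosome (0.06, 0.2) and glycolysis (0.12, 0.16).

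0 genes passed limma's test between these groups, 559 had an unadjusted p under 0.05 where chance gives 817, and 0 passed with voom weights, with library weights or in the authors' table. Among the genes with the smallest p (adjusted p of 0.89 each) were the DNA repair gene Fancd2 (0.76), the spindle checkpoint gene Mad2l1 (0.94), the histone Hist1h4f (0.47), Mut (0.60), Trim7 (-1.31), Sox13 (-1.13) and Mmp15 (-0.84). Arr3, Ptgds and Hrc were near the floor in the doubly treated tumors, with 0 to 7, 0 to 1 and 0 to 6 reads per library, against 16 to 32, 10 to 18 and 9 to 75 reads with ADI-PEG20. Tmem151b and Il23r, also among the smallest p, were scarce with ADI-PEG20, at 5 to 9 and 4 to 16 reads, against 21 to 62 and 17 to 41 with both drugs. The libraries did not overlap for 9.16% of genes, where chance gives 10%.

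Adding ADI-PEG20 to chloroquine went with higher macrophage, stress response, lysosome and cytokine transcripts. Macrophage markers rose by 0.55 with 18 of 19 higher, Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) at 1.31 (SE 0.26), the scavenger receptor Msr1 at 0.97 (SE 0.29) and C1qc at 0.64 (SE 0.18). Stress response targets rose by 0.43 with 25 of 28 higher, Cth at 2.18 (SE 0.52) and the serine synthesis enzyme Phgdh at 0.63 (SE 0.20). Lysosome genes rose by 0.21 with 29 of 36 higher, Mitf at 0.84 (SE 0.22) and Gpnmb at 0.72 (SE 0.21), and inflammatory cytokines by 0.48 with 14 of 18 higher, Ccl2 at 1 (SE 0.29) and Ccl7 at 0.87 (SE 0.23). By camera, the adjusted p was 2.5e-11, 2.3e-07, 0.000011 and 0.00012, with an adjusted p = 0.24 for macrophages and an adjusted p = 0.42 for the others with an estimated correlation. Adjusted over the list alone 8, 1, 0 and 3 members passed, and 0 over all genes. Without doubly treated 3 the cytokine mean was 0.29 (adjusted p = 0.012).

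Muscle genes were lower when ADI-PEG20 was added to chloroquine. The 10 myogenic progenitor genes were all lower, by a mean of -1.73, Myog at -2.89 (SE 1.04) and Chrna1, a subunit of the muscle acetylcholine receptor, at -0.79 (SE 0.25), and 6 passed adjusted over the list alone. The 17 skeletal muscle genes were all lower, by -2.69, Acta1 at -3.32 (SE 1) and Actn3 at -3.04 (SE 1.07). In camera's test the adjusted p was 6.6e-08 and 2.5e-11, with an adjusted p = 0.24 for progenitors and an adjusted p = 0.42 for muscle with an estimated correlation. The list means with chloroquine alone were 4.63 (SD 0.46, n = 3) and 4.69 log2 CPM (SD 0.41, n = 3), and 2.91 (SD 0.22, n = 3) and 2 (SD 0.82, n = 3) with both drugs.

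A further 6 lists passed between the doubly treated and the chloroquine tumors, each with a call that single libraries ended. They were amino acid transporters (0.27, camera adjusted p = 0.019), neutrophils (0.89, 0.014), adipocytes (0.99, 0.013), keratinocytes (0.99, 0.0086), RNA quality and mitochondrial transcripts (0.28, 0.0092) and extracellular matrix (-0.12, 0.014). With an estimated correlation the adjusted p = 0.49 for transporters, the adjusted p = 0.6 for neutrophils and keratinocytes, the adjusted p = 0.61 for adipocytes, the adjusted p = 0.72 for RNA quality and the adjusted p = 0.76 for matrix. Slc7a3 was at 2.01 (SE 0.47) but Slc43a1, a transporter of branched amino acids, at -1.43 (SE 0.45). Tnc was at -0.93 (SE 0.21), Lum at -0.84 (SE 0.23) and the stromelysin Mmp3 at 1.48 (SE 0.48), and Krt14 was at 2 (SE 0.59). Adjusted over the list alone 4 transporters, 2 matrix genes and 1 adipocyte gene, the lipase Lpl (1.63, SE 0.33), passed. Without chloroquine 1 no longer called were matrix (-0.06, adjusted p = 0.15), neutrophils (0.76, 0.072) and RNA quality (0.19, 0.083), and without chloroquine 2 transporters (0.20, adjusted p = 0.082), adipocytes (0.58, 0.089) and keratinocytes (0.65, 0.069), with matrix at -0.21. Without chloroquine 3 the transporter call ended (0.27, adjusted p = 0.054). Without doubly treated 1 the adipocyte mean was 0.28 (adjusted p = 0.28) and that of keratinocytes 1.55. Without doubly treated 2 no longer called were matrix (-0.06, adjusted p = 0.15), keratinocytes (0.07, 0.31) and RNA quality (0.17, 0.15), and without doubly treated 3 transporters (0.18, adjusted p = 0.2) and neutrophils (0.50, 0.33).

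Mmp15 had the smallest p of any gene in this contrast, lower by 1.66 (SE 0.23, adjusted p = 0.099). The next, each with an adjusted p of 0.49, were the Fc receptor Fcgr3 (0.86, SE 0.16), Mrc1, the matrix protein Efemp1 (1.08), Lpl, the platelet chemokine Ppbp (3.22, SE 0.71) and the selenium carrier Selenop (0.94) among those higher. Those lower were Ntn1 (-1.14), Tmem132c (-2.08), Ccdc8 (-1.13), the fibrillin Fbn2 (-1.65, SE 0.35) and Gnao1 (-0.81, SE 0.17). In limma's test 0 genes passed and 1107 had an unadjusted p under 0.05 (508 higher, 599 lower), where chance gives 817. Mmp15 passed without ADI-PEG20 3 (-1.66, adjusted p = 0.032) and in the authors' table, where its log2 fold change was -1.74 (adjusted p = 0.00659). Other fits called 0 genes with voom weights, 1 with voom and library weights, 15 with library weights, 72 with only the 2 groups in the fit, and 22 without ADI-PEG20 1 and untreated 2. The libraries did not overlap for 18.4% of genes, where chance gives 10%.

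The interaction contrast asked whether the effect of ADI-PEG20 differed between tumors with and without chloroquine. Glycolysis and hypoxia genes were lower with ADI-PEG20 alone and not with ADI-PEG20 on top of chloroquine: the interaction was 0.58 for glycolysis with 17 of 17 positive, and 0.86 for hypoxia with 13 of 15 positive. Slc2a1 had an interaction of 1.28 (SE 0.52), Bnip3 of 1.44 (SE 0.53) and P4ha1 of 0.97 (SE 0.27). The interferon gamma list (-0.94, 21 of 22 negative) and T cell markers (-1.24, 18 of 18 negative) had negative interactions, with Cxcl9 at -2.06 (SE 0.64). Camera gave an adjusted p of 2.3e-07, 1e-06, 2.1e-07 and 0.0000041 in that order, and each had an adjusted p = 0.64 with an estimated correlation. Without chloroquine 3 the interferon gamma interaction was -0.54 and that of T cells -0.81. In all 14 lists passed by camera, 8 positive and 6 negative, and 0 with an estimated correlation. Of 100 regroupings of the libraries, the real one included, 36 called as many.

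0 genes had an interaction in limma's test, 696 had an unadjusted p under 0.05 where chance gives 817, and 0 passed with voom weights or library weights. The smallest p (adjusted p of 0.82 each) belonged to Ampd3 (0.98), Apob (2.57), P4ha1, Mmp10 (3.18), AW549877 (0.84) and Zc3h12c (1.13) among positive values and to Mest (-1.34), P2rx5 (-1.81), Zfp61 (-1.53), Pkdcc (-1.14), Exosc5 (-1.13) and Cyp2j6 (-2.72) among negative ones. Across the 16335 genes, the log2 differences for ADI-PEG20 without and with chloroquine had r = 0.189 (exact permutation p = 0.24 over 400 relabelings, smallest possible 0.005), and those for chloroquine without and with ADI-PEG20 r = -0.0409 (exact permutation p = 0.7). Genes are not independent replicates in these correlations.

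11 lists passed in none of the 6 contrasts. With ADI-PEG20 against no treatment their mean differences were 0.00 for arginine and urea cycle enzymes (camera adjusted p = 0.99), -0.18 for polyamine metabolism (0.11), 0.02 for autophagy (0.84), -0.08 for macropinocytosis (0.56), 0.08 for phospholipase A2 (0.58), 0.12 for angiogenesis (0.28), 0.13 for endothelial cells (0.1), -0.06 for pericytes (0.79), 0.39 for fibroblasts (0.27), 0.48 for mast cells (0.73) and 0.46 for Schwann cells (0.071). With both drugs arginine and urea cycle enzymes differed by 0.01 (0.66), autophagy by 0.03 (0.71) and macropinocytosis by -0.02 (0.71). The macropinocytosis list holds Cav1, a gene that varied between tumors with its neighbors on chromosome 6. Medians and means of lists that did not pass had opposite signs in places, such as mast cells (-0.02 and 0.48) and extracellular matrix (-0.04 and 0.01) with ADI-PEG20 and pericytes (-0.04 and 0.06) with chloroquine. With both drugs against no treatment this held for phospholipase A2 (-0.08 and 0.17), angiogenesis (-0.08 and 0.06), endothelial cells (0.09 and -0.01) and mast cells (-0.20 and 0.18), against ADI-PEG20 for autophagy (-0.03 and 0.01) and natural killer cells (-0.03 and 0.25), and in the interaction for chaperones (-0.01 and 0.02). The test pointed up where both were negative or 0 for macropinocytosis and Schwann cells with both drugs (-0.07 and -0.29) and for fibroblasts against each single drug, and down for oxidative phosphorylation against chloroquine (0.02 and 0.00) and arginine enzymes with ADI-PEG20 (-0.03 and 0.00). All lists that passed had the same sign in median, mean and test.

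The deposited KEGG results also placed immune sets among the highest with ADI-PEG20 and with both drugs. With ADI-PEG20 the authors' table has 15 sets past a false discovery rate of 0.05, all higher, led by cell adhesion molecules (statistic 5.128, 112 genes), antigen processing and presentation (5.094, 63 genes) and hematopoietic cell lineage (5.048, 71 genes), each with a rate of 0.0000578. With both drugs it has 18 sets, all higher, among them hematopoietic cell lineage (5.126, rate 0.000119) and antigen processing and presentation (4.352, rate 0.00131). With chloroquine it has 1, the ribosome, lower (-3.88, rate 0.0162). The authors' gene table has 0 genes past an adjusted p of 0.05 in 4 of the 5 group comparisons tested here and 1, Mmp15, in the other (its comparison of chloroquine with ADI-PEG20 was not examined), with unadjusted p under 0.05 for 949 genes with ADI-PEG20, 475 with chloroquine, 1635 with both, 394 for both against ADI-PEG20 and 2242 for both against chloroquine.

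A block of neighboring genes on chromosome 6, chosen after its values were seen, varied more between tumors than between groups. Tes, Cav2, Cav1, Met, Capza2 and St7 (chromosome 6, 17065149 to 17943025, GRCm38), which include the receptor for hepatocyte growth factor and the caveolins, averaged 10.01, 10.01 and 7.20 log2 CPM in untreated tumors and 6.40, 8.40 and 8.31 with chloroquine. They averaged 5.79, 9 and 8.92 with ADI-PEG20, and 6.71, 10.15 and 6.73 with both drugs. Met alone ran from 100 CPM in ADI-PEG20 1 to 3620 CPM in untreated 2. The 15 pairs of these genes had a median r of 0.957 over the 12 libraries (lowest 0.676, for a block picked because it varied together), and the group means did not differ in a permutation test (p = 0.72, 100000 permutations). In untreated 2 the genes Mios, Rpa3, Umad1, Glcci1 and Lsm8 of the same chromosome lay 4.39, 4.08, 4.43, 5.14 and 4.13 above the median of the other libraries, while Tes lay at -1.57.

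**Figure D3:**
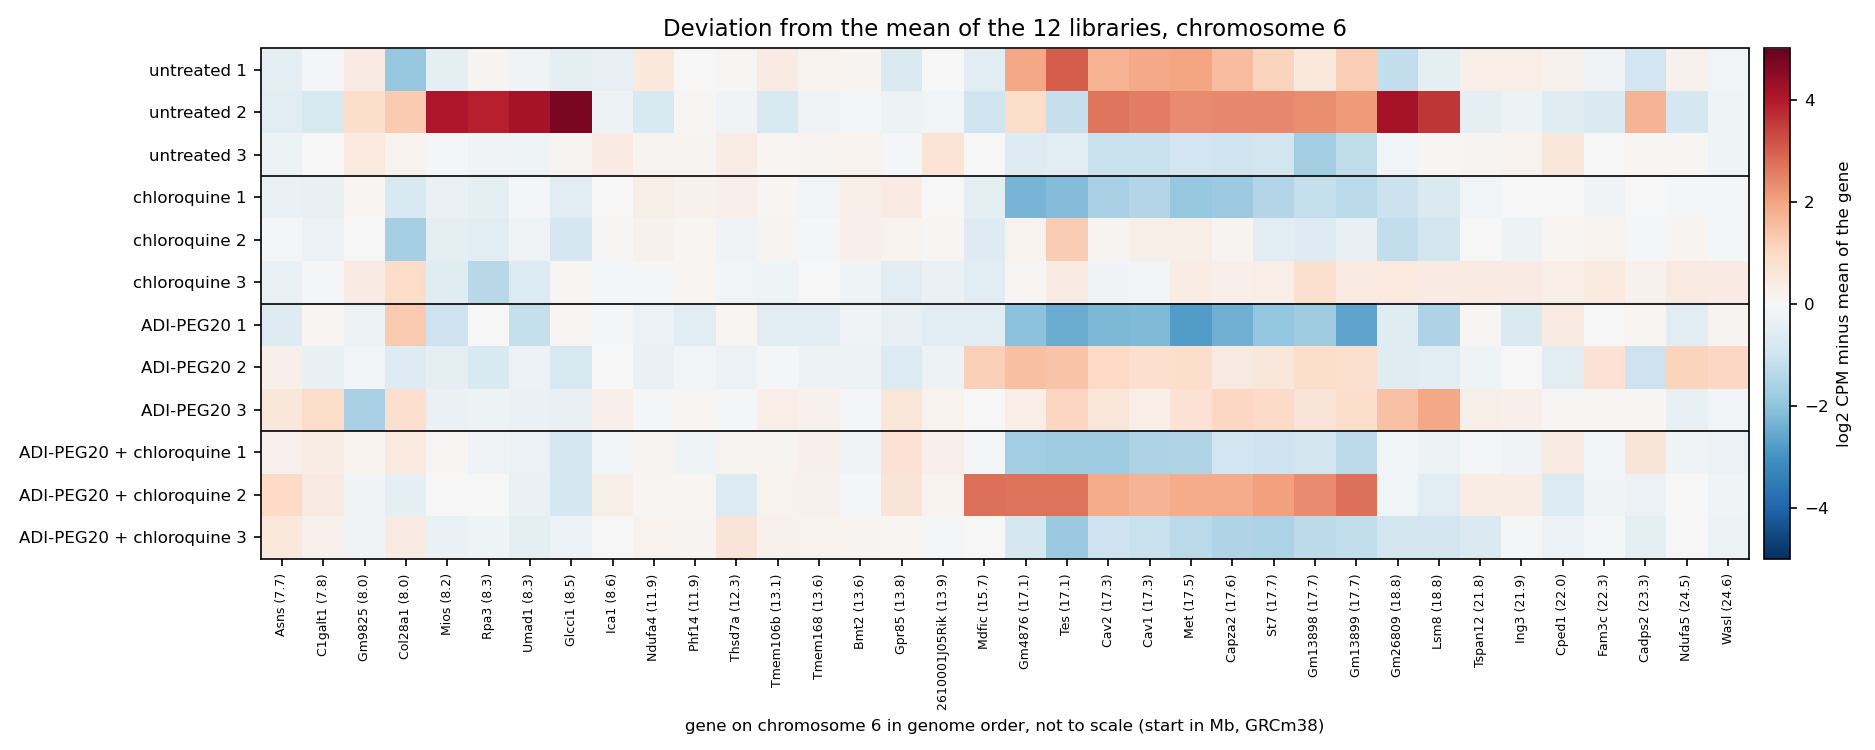
Log2 CPM minus the mean of each gene over the 12 libraries (color), for genes of chromosome 6 in genome order (x axis, not to scale, start in Mb on GRCm38) and the 12 tumor libraries (y axis, grouped by treatment). The block from Tes to St7 is high in untreated 1 and doubly treated 2 and low in ADI-PEG20 1, while untreated 2 is high from Mios to Glcci1, from Cav2 to St7 and at Lsm8 but below the mean at Tes.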

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

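The interaction contrast and its gene lists were planned, as were the counts over regroupings; the fit without ADI-PEG20 1 and untreated 2 was chosen after the results were seen. 14 gene lists passed the test of whether the effect of ADI-PEG20 differs between tumors with and without chloroquine, and each is given here as the mean interaction on the log2 scale with its camera adjusted p.

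Metabolic and growth genes had positive interactions, most of them lower with ADI-PEG20 alone and not when it was added to chloroquine. The interaction was 0.58 for glycolysis (adjusted p = 2.3e-07), 0.86 for hypoxia response (1e-06), 0.32 for G1 to S (0.00023), 0.19 for oxidative phosphorylation (0.0081), 0.24 for cholesterol synthesis (0.037), 0.21 for pyrimidine and purine synthesis (0.039), and 0.36 for RNA quality and mitochondrial transcripts (0.0062). With an estimated correlation the adjusted p = 0.64 for the first 3, the adjusted p = 0.66 for oxidative phosphorylation and RNA quality, and the adjusted p = 0.7 for cholesterol and nucleotide synthesis. Without untreated 1 no longer called were oxidative phosphorylation (0.09, adjusted p = 0.22), cholesterol synthesis (0.14, 0.22), nucleotide synthesis (0.12, 0.25) and RNA quality (0.20, 0.061), and without ADI-PEG20 1 the same 4 lists (0.10, 0.099; -0.02, 0.76; 0.09, 0.26; 0.12, 0.11). Without chloroquine 3 no longer called were oxidative phosphorylation (0.13, adjusted p = 0.092), cholesterol synthesis (0.09, 0.43) and nucleotide synthesis (0.12, 0.25), with G1 to S at 0.21. Nucleotide synthesis also lost its call without ADI-PEG20 3 (0.20, adjusted p = 0.14), doubly treated 1 (0.17, 0.095) or doubly treated 2 (0.20, 0.055), and cholesterol synthesis without doubly treated 1 (0.25, 0.064). Without ADI-PEG20 2 the nucleotide and cholesterol means were 0.33 and 0.41, without chloroquine 2 the cholesterol mean was 0.39, and without untreated 2 RNA quality was at 0.56.

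4 immune lists had negative interactions, with a rise under ADI-PEG20 alone that was smaller or absent when it was added to chloroquine. On top of chloroquine the differences were 0.10 (interferon gamma), -0.19 (type I interferon), -0.12 (T cells) and 0.17 (dendritic cells). In that order the lists were also higher than untreated with chloroquine alone (0.70, 0.67, 0.73 and 0.50) and with both drugs (0.80, 0.48, 0.61 and 0.67). The same untreated libraries enter these last differences and the interaction. The interaction was -0.94 for interferon gamma response and antigen presentation (adjusted p = 2.1e-07), -0.69 for type I interferon response (2.1e-07), -1.24 for T cells (0.0000041) and -0.66 for dendritic cells (0.019), each with an adjusted p = 0.64 with an estimated correlation. Without chloroquine 3 the means were -0.54 for the interferon gamma list, -0.81 for T cells and -0.32 for dendritic cells, the last no longer called (adjusted p = 0.17). Dendritic cells also lost their call without untreated 2 (-0.59, adjusted p = 0.059) or doubly treated 2 (-0.47, 0.066), and the type I interferon mean was -0.43 without untreated 2 and -0.37 without doubly treated 2.

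Transcripts of muscle and red blood cells made up the rest. The interaction was -2.36 for skeletal muscle (adjusted p = 0.00001), -1.71 for myogenic progenitors (0.0064) and 1.91 for erythroid cells (0.0021), each with an adjusted p = 0.64 with an estimated correlation. Skeletal muscle was at -1.19 without untreated 2, -0.81 without ADI-PEG20 1, and 0.35 without both (adjusted p = 0.5), so that its direction rested on these libraries. The progenitor call ended without ADI-PEG20 2 (-1.52, adjusted p = 0.13), and the erythroid mean was 1.22 without doubly treated 1.

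Random regroupings of the 12 libraries gave results as large for the interaction, so chance was not excluded for its counts. With the real grouping included, 36 of 100 regroupings called as many lists as the real 14, with a highest other count of 22, and 37 of 100 had as many genes at an unadjusted p under 0.05 as the real 696, with a highest other count of 2295. The make-up of the regrouping with 2295 genes was not recorded. A regrouping of all 12 libraries can bring the effect of ADI-PEG20 itself into the contrast. Its count therefore does not show a structure of the tumors other than the treatment groups.

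For the comparisons of 2 groups, the 6 libraries make 10 splits, too few for a share under 0.05, and the counts below include the real split. With ADI-PEG20 against no treatment, 1357 genes had an unadjusted p under 0.05 (highest other split 2090, 6 of the 10 at least as many) and 16 lists were called (highest other 21, 2 of the 10 as many). The split with 2090 genes put ADI-PEG20 1, ADI-PEG20 3 and untreated 3 on one side. With chloroquine there were 555 genes (highest other 1532, 7 as many) and 9 lists (highest other 18, 9 as many). The split with 1532 genes put chloroquine 1, chloroquine 3 and untreated 3 on one side. Both of these splits put the libraries numbered 3 on one side and those numbered 2 on the other. The highest other gene counts for both drugs against no treatment and against chloroquine came from splits of the same kind. That for both drugs against ADI-PEG20 did not. Whether this pattern reflects a structure of these tumors was not tested. With both drugs against no treatment there were 1413 genes (highest other 1399, 1 as many) and 18 lists (highest other 18, 2 as many). Against ADI-PEG20 there were 559 genes (highest other 1091, 8 as many) and 12 lists (highest other 16, 8 as many), and against chloroquine 1107 genes (highest other 737, 1 as many) and 12 lists (highest other 18, 8 as many).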

How the results depend on the processing

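The voom fits, the fit without ADI-PEG20 1 and untreated 2, and the other scaling for gene lists were chosen after the data were seen. All other alternatives were planned, the other scaling for single genes included. Counts of passing genes were 0 in every comparison and alternative run, with these exceptions, whose cause was not tested. For both drugs against no treatment, 8 genes passed with the replicate number as a block (Ntn1, Fam129a, Cth, Slc7a3, Gnao1, Mmp15, Adm2 at 2.35 and Actg2 at -1.63, adjusted p from 0.042 to 0.047), and 17 without ADI-PEG20 1 and untreated 2. For both drugs against chloroquine, 72 passed with only the 2 groups in the fit, 15 with library weights (Mmp15 at an adjusted p of 0.0048, the other 14 at 0.049), 1 by the authors' adjusted p, 1 with voom and library weights, and 22 without the 2 libraries. Library weights were lowest for ADI-PEG20 1 (0.283) and untreated 2 (0.516). Leaving out 1 library at a time gave 0 to 1 genes for ADI-PEG20 against no treatment and for both drugs against chloroquine, and 0 to 0 for the others.

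The number of gene lists called fell to 0 in all 6 contrasts with an estimated correlation, which allows for genes of a list that vary together between tumors. By fry, which tests a list on its own and not against other genes, it was 0, 0, 2, 0, 0 and 0 in the order ADI-PEG20, chloroquine and both against no treatment, both against ADI-PEG20, both against chloroquine, and interaction. Leaving out 1 library gave 15 to 21, 9 to 16, 12 to 21, 9 to 17, 10 to 19 and 11 to 19 lists in that order. Of 81 list results, all kept their direction and call under another scaling and with the replicate block, and 59 without the 2 libraries, where 21 lost their call. Over the fits that leave out 1 library, 868 list results kept their call and 103 lost it. With the cause not tested, the direction of the list test reversed for the chaperone list for both drugs against no treatment (0.00 without untreated 2, up to 0.24 without untreated 1) and the skeletal muscle interaction (0.35 without the 2 libraries). The mean alone changed sign, in lists that lost their call, for adipocytes with ADI-PEG20 against no treatment (-0.17 without the 2 libraries), oxidative phosphorylation for both drugs against no treatment (0.02 without untreated 1), RNA quality for both against ADI-PEG20 (-0.01 without ADI-PEG20 1, with or without untreated 2) and the cholesterol interaction (-0.02 without ADI-PEG20 1).

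Of 84 results for named genes, all kept their direction and side of the threshold with voom weights and under another scaling, which moved the median difference of all genes by at most 0.009. Leaving out 1 library kept 999, let 1 pass and reversed 8, all small values of the knocked out genes, cause not tested: Trp53 for chloroquine (-0.12) and both drugs (-0.02) against no treatment without untreated 1, and for both against chloroquine without chloroquine 1 (-0.03) or doubly treated 1 (-0.01). Ass1 for both against chloroquine was 0.12 without chloroquine 3 and 0.04 without doubly treated 1, and for both against ADI-PEG20 -0.21 without ADI-PEG20 3 and -0.21 without doubly treated 3. The opposite ends of those ranges were 0.4 and 0.49 (without untreated 3) and 0.22 (without chloroquine 3) for Trp53 in that order of comparisons, -0.35 (without doubly treated 3) for Ass1 against chloroquine and 0.22 (without ADI-PEG20 1) for Ass1 against ADI-PEG20. The stricter filter kept the 73 results whose genes it retained. Not run were pseudocounts and the absence of a filter, since the deposited values are already on the log2 scale and lack low genes, and a Wald test on the recovered reads. The replicate numbers were not taken as pairs, since not every pair of libraries sharing one had r above 0.1. The 18 such pairs had r from -0.0499 to 0.199 (median 0.0972, against -0.0391 for 36 pairs with other numbers), 9 of them above 0.1. These r compare deviations from group means, which cancel within a group, so higher values for one kind of pair force lower ones for the other. The value for pairs with other numbers is therefore no independent reference. Of 12 libraries, 3 correlated best with their own number in every group. A rule that asks for every pair does not exclude a weaker link between libraries that share a number. Depth limits scarce transcripts, such as lymphocyte markers: 1 read was worth up to 0.0794 CPM.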

Other observations

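The effects over both states of the other drug, the tests on chromosome 6, those on ADI-PEG20 1 and those on macrophage and stress response genes were chosen after the results were seen; the count of regroupings for the first was written before its result. Over both chloroquine states, 6 tumors with ADI-PEG20 and 6 without, macrophage markers were higher by 0.53, amino acid transporters by 0.36 and stress response targets by 0.39. Among genes, Slc7a3 was higher by 2.23 (SE 0.33), the lipoprotein lipase Lpl by 1.51 (SE 0.24) and Ank2 by 0.60 (SE 0.10), and lower were Mmp15 (-1.12, SE 0.16), Ntn1 (-1.04, SE 0.16), Tnc (-0.94, SE 0.15) and Gnao1 (-0.75, SE 0.12). Each had an adjusted p of 0.065 in limma's fit, so 0 genes passed, with 1601 at an unadjusted p under 0.05. Of 100 regroupings within chloroquine states, out of 200 possible and with the real one included, 9 gave as many genes (highest other 2539), so chance was not excluded. For chloroquine over both ADI-PEG20 states 0 genes passed, 365 had an unadjusted p under 0.05, and the smallest adjusted p was 1.

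Muscle transcripts differed between tumors more than any other list examined here, and their most abundant genes were chosen after their values were seen. Myh4, a fast myosin, was at 973 CPM in untreated 1 and 1040 CPM in ADI-PEG20 1, against 0.107 to 29.9 CPM elsewhere. Titin, Ttn, ran from 318 to 4970 CPM. The SD of the skeletal muscle list was 2.17 in untreated, 0.41 in chloroquine, 2.71 in ADI-PEG20 and 0.82 log2 in doubly treated tumors (n = 3 each).

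6 neighboring genes on chromosome 6, from Tes to St7, varied together between tumors by up to 3.44 log2 within a group. Treatment does not account for that spread, which was 2.81, 2, 3.21 and 3.44 within the 4 groups, and the groups did not separate (permutation p = 0.72). A varying share of tumor cells would move many genes elsewhere in the genome, but 3 of 11181 genes outside chromosome 6 followed the block with r above 0.9 and a slope of at least 0.5. In 1000 shuffled gene orders 0 had 6 neighbors with as high a mean covariance (highest 0.690, against 2.3 here), which argues against the best of many windows by chance, though a myosin cluster on chromosome 11 (2.391) varied together as much. A gain or rearrangement of this region, Met included, in part of the tumors is a candidate explanation that no genomic data here tested.

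ADI-PEG20 1 had the lowest correlation with the other libraries and low depth. Thinned to the reads of the smallest library without Gm26917, 12504222 reads each, it stayed lowest by 0.0137 (range over 10 thinnings 0.0014), so depth alone does not account for it. More host tissue of every kind would raise all cell type lists. Each SE in this paragraph is over the genes of a list, so it does not measure the spread between tumors. Of 16 lists, 10 lay above both other ADI-PEG20 tumors. Neutrophils (-1.67, SE 0.30), keratinocytes (-1.45, SE 0.55) and natural killer cells (-1.41, SE 0.62) lay below both, which argues against it in this library alone. These 3 lists are scarce, with 6 of 9, 4 of 12 and 2 of 8 genes under 10 reads in this library, where their sums were 398, 827 and 119 reads against 640, 979 and 286 expected from the other tumors. All 24 measured skeletal muscle and adipocyte genes lay above both other tumors, muscle by 4.62 (SE 0.40) and fat by 3.09 (SE 0.77). Without these 24 genes ADI-PEG20 1 stayed lowest by 0.0134 (0.0139 with them). A correlation over all genes can hardly change when 24 are left out, and any other transcripts of muscle or fat stay in it. The small change therefore does not show how much muscle or fat tissue adds to the distance of this library. Whether muscle or fat tissue or myogenic differentiation raised the 24 genes stays open.

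Macrophage markers, stress response targets and amino acid transporters were higher with ADI-PEG20 over both chloroquine states (camera adjusted p = 9.4e-15, 2.7e-08 and 0.000032, or adjusted p = 0.22, 0.29 and 0.29 with an estimated correlation, and 0.047, 0.18 and 0.06 by fry). Of 15 other cell type lists 3 stayed below the macrophage list by more than 2 SE, but myogenic progenitors (-1.4, SE 0.43) may come from the tumor line itself, and of the 13 lists without muscle 2 remained, pericytes (-0.73, SE 0.13) and endothelial cells (-0.42, SE 0.15). Pericyte genes could also come from a mesenchymal tumor, so a lower share of tumor cells stays open. The 2 doubted libraries do not account for it: without them the lists kept at least 92.6% of the difference (macrophages 0.49, against 0.53). Treatment with ADI-PEG20 and chance cannot be told apart here: the exact permutation p was 0.005 for macrophages, the smallest that 400 relabelings can give, and 0.01 for each other list, but 0.13 adjusted over 38 lists, where the number of relabelings limits the outcome: 1 list at the smallest p reaches 0.19, and fewer than 4 lists cannot pass.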
